A study of Homo sapiens with 2 samples.

How the data were processed

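RNA of human neural progenitor cells was hybridised to 2 Agilent 2-colour whole-genome arrays, each with HSF6 EB cells in Cy3 and HSF1 cells in Cy5, per the labels. The direction of every ratio, HSF1 over HSF6, follows from these dyes. The authors deposited the scanner output of each array, extracted with Agilent Feature Extraction 9.5.1.1 from array design 012391 with a grid on genome build hg17, per the file headers. The spot brightness is deposited as intensity on a linear scale, as a mean signal and a local background per channel. The scanner software's own ratio is deposited as log10 of Cy5 over Cy3, after background subtraction and linear and lowess dye normalization, per the file headers. Its error is a score deposited on the same scale, from the scanner software's error model. Marks for spots well above background, saturated or outlying were deposited too. The deposited series table holds values that match that log10 ratio to 0.0050 at most, in scale and direction, with a median of 0 on both arrays, so they are the rounded scanner ratios.

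Intensities were background corrected with normexp (offset 50) and normalized within each array by loess with limma 3.58.1 in R 4.3.3. The 2256 control spots had weight 0 in the loess and were left out afterwards, as were 84 outlier-marked gene spots on the first array and 57 on the second. Saturated spots were kept, at most 3 per channel. Spots of a probe were averaged. Single channels were compared between arrays after quantile normalization of the average signal. The third comparison is the second array's log2 ratio minus the first's, with scanner errors combined as the root of the sum of squares. The offset shrinks the ratios of dim genes.

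Probes were named through the RefSeq gene table of another assembly, used for names only. Of 40975 probes with an unmarked spot, 23421 matched through an accession, 2315 through a symbol and 1042 through an older symbol, which gave 17458 genes. Another 10937 probes kept only the name in the files and 3260 had none, and these are not counted as genes. Of 10194 such transcripts with a name of their own, 58 were higher and 31 lower in the first comparison, 25 and 51 in the second, and 28 and 76 in the third. Left out were 104 probes for X-inactivation transcripts and genes of the Y chromosome. A gene took its brightest probe. Probes of opposite sign were found for 12 of 95 called genes with over 1 detected probe in the first comparison, 4 of 138 in the second and 10 of 91 in the third. Coordinates are those of the probes in the files, and the annotation of exons was not used here.

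With 1 array per comparison there is no test and no p-value. A gene was called higher or lower at a log2 ratio of at least 1 in size, when well above background in at least 1 channel compared, which for the third comparison means Cy5 on at least 1 array. Where only the brighter side was well above background on the compared channels, "at least N-fold" sets it against the higher of the dim probe's own signal and the lowest signal of any probe well above background in that channel, and such bounds are open to dye bias. A list's median with such genes at their bound is given where it differs by over 0.1. For the third comparison bounds compare the Cy5 channels. The 20 gene lists, the size rule, the alternatives and the rule for named genes were fixed before the data were examined, except where a choice is said to come later. Each list's median was placed among 10000 random lists of the same size matched on mean expression in 20 bins, as a description of these arrays. Named genes are, per comparison, the 6 highest and 6 lowest whose detected probes share a sign, the 4 members with the largest ratios of each of the 4 regional lists and the 2 largest of every other list. Some genes that this rule names are not reported here. HOXB4 and HOXB5 in the third comparison and IGF2 were named after their values were seen.

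The normalization was tested on simulated arrays with 50 changed probes per size. A log2 ratio of 1.5 passed the size rule for 72% of probes on the first array and 64% on the second, and one of 3.0 passed for 100% on both, with 0 of 21984 and 0 of 18190 unchanged probes past it. The changed probes were drawn only from brighter spots well above background in Cy3, so these shares do not cover dim probes. The simulated arrays held small spot noise and a smooth dye effect only. They held no dye bias of single probes and no difference between cultures or arrays. The counts of 0 therefore give no rate of false calls for the real arrays. The list percentiles were also run on simulated lists, whose outcome is not given here, so no error rate is claimed for them. Figures and tables used Python 3.11.15, pandas 2.3.3, numpy 2.4.6, scipy 1.17.1 and matplotlib 3.10.9. Alternatives were no background correction, an offset of 0, the scanner software's log ratio, the series table, median centring, stricter and absent background filters, marked spots kept, the mean of a gene's probes and, for the third comparison, the Cy5 signals alone. Added after the data were examined were the HSF6 channel of the other array, the removal of clustered bright spots, and the BMP targets without the list's ligands and inhibitors. Medians of raw Cy3 and Cy5 intensity were 99.3 and 76.1 on the first array and 96.3 and 64.7 on the second, against medians of 76.9, 51.4, 83.2 and 50.3 for 314 negative control spots, so that dim genes carry little information.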

Results

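Transcripts were profiled in neural progenitor cells derived from HSF1 and HSF6, which are established human embryonic stem cell lines. The progenitors had been made by one of 2 routes. In the embryoid body (EB) route, aggregates of stem cells were exposed to retinoic acid and basic FGF, factors that give neural cells a posterior identity. In the monolayer route, attached cells were converted with Noggin, a secreted inhibitor of BMP signalling. The first array compared HSF1 EB with HSF6 EB cells and the second compared HSF1 monolayer with HSF6 EB cells. HSF6 cells made with Noggin were not analysed here. HSF1 carried Cy5 and HSF6 carried Cy3 on both arrays, so that cell line and dye could not be told apart in a single ratio. Each of the 3 comparisons rests on 1 sample per side, with no replicate and no dye swap, and the number of arrays limits the precision. No test could be made. Ratios are log2, from the normalization above. Each ± is the scanner software's error of its own log ratio, not of the ratio printed beside it. The scanner's ratios of dim genes are often larger in size, such as -1.55 for KDR where -0.31 is printed in the first comparison. This error covers the measurement of the spots and not the spread between cultures. Higher and lower by at least 2-fold are statements of size only.

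Each array held 41675 gene spots for 41000 probes. On the first array 53.2% of the gene spots were well above background in Cy3 and 51.2% in Cy5. The second array was dimmer, with 44.1% in Cy3 and 43.9% in Cy5. Among 75 probes spotted at least 5 times, the pooled SD of the log2 ratio was 0.11 on the first array and 0.07 on the second. The HSF6 EB signal, measured on both arrays, differed by at least 2-fold for 264 of 11801 detected genes, 212 of them dimmer on the second array and 52 brighter. The labels do not say whether the same HSF6 RNA was used for both arrays. Across 11039 detected genes the differences between the arrays in Cy3 and in Cy5 were correlated, with r of 0.54. Ratios given below against the HSF6 channel of the other array take in any array difference shared by both dyes, which cancels within an array. A call lost in that way may therefore reflect the arrays rather than the HSF6 material.

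The first comparison asked how progenitors of the lines differed when both were made by the EB route. HOX genes, which set position along the hindbrain and spinal cord, were lower in HSF1 EB than in HSF6 EB cells. Of 18 detected HOX genes 11 were lower by at least 2-fold and 0 were higher, and the list's median log2 ratio of -1.34 lay below those of all 10000 random lists matched on expression, whose central 95% ran from -0.19 to 0.13. HOXA4 was at least 8.68-fold lower, and HOXB4, HOXB3 and HOXB5 had ratios of -2.86 ± 0.44, -2.49 ± 0.32 and -2.32 ± 0.39. The HSF6 signal of the list differed by -0.54 in the median, second minus first array, and against the second array's HSF6 channel the HOX median was -0.85, with HOXA4 at -2.23, HOXB4 at -1.63, HOXB3 at -1.84 and HOXB5 at -0.77. Over all HOX genes on the array, with no filter on background, the median was -0.30. No forebrain gene passed 2-fold by this route, with 8 of the 28 on the array detected and a median of -0.07, at percentile 31.5 of random lists. ZIC1 came closest, at 0.99 ± 0.22.

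Other regional and signalling groups differed less between HSF1 EB and HSF6 EB cells. Of 10 detected hindbrain and spinal cord genes outside the HOX family, 1 was lower by at least 2-fold, NKX6-2 at -1.14 ± 0.32, which was -0.42 against the second array's HSF6 channel, and their median was -0.06. None of 6 midbrain and isthmus genes passed 2-fold. Their median was 0.31, at percentile 99.4, with EN2 at 0.78 ± 0.22, and it was 0.21 with genes at their bound and -0.15 over those well above background in both channels. In the retinoid list 2 of 12 genes were higher and 1 was lower. CYP26A1, an enzyme that degrades retinoic acid, had a ratio of 2.66 ± 0.39, and of 1.39 against the second array's HSF6 channel, where its HSF6 signal was 1.27 higher. In the BMP list, of ligands, inhibitors and targets, 2 of 16 genes were higher, the targets BAMBI at 1.02 ± 0.23 and ID4 at 1.02 ± 0.23, and the list's median of 0.44 lay above all random lists. Against the second array's HSF6 channel these genes stood at 0.67 and 0.86. The median of the 9 targets alone was 0.54. Of 14 genes of the Wnt, FGF and SHH list 2 were higher, with FOXA1 at least 2.61-fold and SP5, a Wnt target, at least 2.14-fold, and a median of 0.47, also above all random lists. SP5 stood at 0.75 against the second array's HSF6 channel.

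Among cell type groups, the neural progenitor genes HES5, a Notch target, and SOX3 were higher in HSF1 EB cells, at 2.36 ± 0.30 and 1.87 ± 0.27, although another SOX3 probe had the opposite sign. They were 2 of 18 detected in that list, whose median was 0.17. The HSF6 signal of these genes was itself 2.86 and 2.66 higher on the second array. Against that channel their ratios were -0.50 and -0.79 and the list's median was -0.22. In the neuron list 1 of 19 genes, the adhesion molecule CNTN2, was lower at -1.79 ± 0.28, and the median was -0.42, below all random lists, and 0.017 against the second array's HSF6 channel, where CNTN2 stood at -3.09. Among 8 glial genes GFAP was lower at -2.21 ± 0.30 and PDGFRA was higher at 2.02 ± 0.31, with a median of -0.11. The neural crest genes TWIST1 and PAX3 were higher, at 1.72 ± 0.28 and 1.52 ± 0.28, among 9 detected with a median of 0.38, or 0.25 with genes at their bound. Against the second array's HSF6 channel PAX3 stood at 0.10, its HSF6 signal being 1.41 higher there, and TWIST1 at 1.95. All 16 detected cell cycle genes had positive ratios with a median of 0.44, and 1 passed 2-fold, TYMS at 1.04 ± 0.23. The HSF6 signal of the cell cycle list was 0.50 higher, in the median, on the second array, and against that channel the list's median was -0.13 and TYMS stood at 0.45.

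Genes of non-neural tissues went both ways between HSF1 EB and HSF6 EB cells. In the mesenchyme list 4 of 13 genes were lower, among them fibronectin (FN1) at -1.53 ± 0.25, and 1 was higher, the transcription factor FOXC1 at 3.48 ± 0.40, with a list median of -0.57. The HSF6 signal of this list differed by -1.14 in the median, second minus first array, and against the second array's channel the list's median was 0.42 and the ratio of FN1 0.63. The imprinted genes MEST and H19 were among 4 of 12 that were lower, MEST by at least 23.7-fold and H19 at -3.14 ± 0.39, while the list's median was 0.01. Against the second array's HSF6 channel H19 turned to 0.71, its HSF6 signal differing by -3.85, and MEST stood at -3.47. IGF2, another of the 4 and named after its values were seen, went from -1.46 to 3.003. Of 4 endoderm genes TTR was higher at 2.95 ± 0.44 and APOA1 at least 3.58-fold lower, with a median of 0.24, and against that channel APOA1 stood at -0.14. Of 6 epithelial and trophoblast genes 2 were lower, including the keratin KRT18 at -1.63 ± 0.26, which was -0.45 against that channel. In addition 1 was higher, CGB3 by at least 2.26-fold, which is uncertain because this gene has near-identical copies and stood at 0.86 against that channel, and the list's median was -0.51. No gene passed 2-fold among 7 pluripotency genes (median 0.03), 12 stress genes (median 0.12), 12 housekeeping genes (median -0.16, with GAPDH at -0.81 ± 0.22) and the single blood and endothelial gene detected, KDR, at -0.31 ± 0.65.

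In all, 141 genes were higher and 222 lower in HSF1 EB than in HSF6 EB cells by at least 2-fold, of 12114 detected. The highest ratios were those of FOXC1, with its probe on chromosome 6 at 1557279 to 1557338 (build hg17), TTR, VENTXP1, CRYM, HMBOX1 and LY6G6E. CRYM was at least 6.40-fold higher, and HMBOX1 had a ratio of 2.73 ± 0.36. VENTXP1 and LY6G6E, at least 7.49-fold and 6.28-fold higher, lie within 3 rows and 3 columns of other bright Cy5 spots on that array. The lowest were those of MEST, with its probe on chromosome 7 at 129739599 to 129739658, the collagenase MMP1 at -3.95 ± 0.57, NNMT at -3.76 ± 0.47, the muscle genes MYBPH at -3.33 ± 0.43 and MYH3 at -3.19 ± 0.39, and HOXA4. The HSF6 signals of MYBPH and MYH3 differed by -4.22 and -4.45, second minus first array, and against the second array's HSF6 channel their ratios were 0.89 and 1.26. Those of MMP1 and NNMT were -1.31 and -1.49 against that channel, their HSF6 signals differing by -2.64 and -2.27, and that of FOXC1 was 5.04.

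The split between higher and lower genes in this comparison depended on the scaling. With the ratios centred on their median in place of loess, 349 genes were higher and 135 lower, 72.1% higher against 38.8%, and the median of detected genes stood at 0.19. Against the HSF6 channel of the second array, 241 genes were higher and 160 lower, and 173 of the 363 genes kept their call. Of the 35 calls among genes chosen by the naming rule, 18 were kept, 11 fell under 2-fold and 6 changed sign. The 18 include VENTXP1 and LY6G6E, at 3.04 and 2.69 against that channel. Only the HSF6 side changes in this setting, so it cannot test bright Cy5 spots such as theirs.

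The second comparison set HSF1 monolayer against HSF6 EB cells, which differ in both cell line and route. Some forebrain genes were far higher in the HSF1 monolayer cells. Of 17 detected 15 had positive ratios, 9 were higher by at least 2-fold and 0 were lower. The median of 1.29 lay above those of all 10000 random lists, whose central 95% ran from -0.18 to 0.16. For 9 of the 17 only 1 side was well above background, a feature on which the random lists were not matched. The transcription factor gene LHX2 was at least 26.2-fold higher, EMX2 at least 20.5-fold and FEZF2 at least 3.49-fold, each with an HSF6 signal not well above background. Over all forebrain genes on the array, with no filter on background, the median was 0.38, and it was 0.72 over those well above background in both channels. HOX genes were lower, with 10 of 14 past 2-fold, 0 higher and a median of -1.77, below all random lists. For 11 of the 14 only 1 side was well above background, so that the direction and the rank among random lists rest partly on the filter. The median was -1.54 with genes at their bound and -0.15 over all HOX genes on the array. HOXB3 and HOXB2 had ratios of -4.11 ± 0.58 and -3.37 ± 0.42, and HOXA2 and HOXA4 were at least 4.02-fold and 3.57-fold lower.

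**Figure D1:**
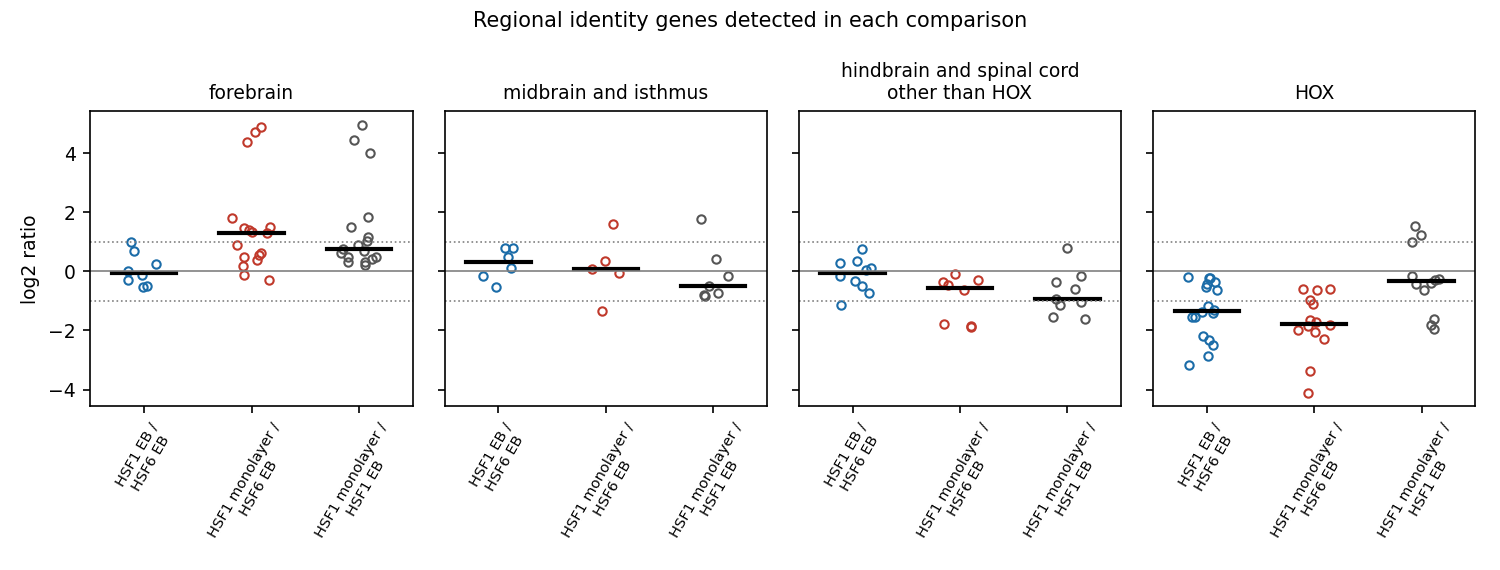
Log2 ratios of the detected genes of 4 regional lists in the 3 comparisons. Each circle is 1 gene, black bars are medians, and dotted lines mark 2-fold, with the forebrain median at -0.07, 1.29 and 0.75 and the HOX median at -1.34, -1.77 and -0.34 from left to right.

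The list of hindbrain and spinal cord genes outside the HOX family had negative ratios as well in HSF1 monolayer against HSF6 EB cells. Of 8 detected all were negative and 3 passed 2-fold, among them MEIS2 at -1.87 ± 0.39 and MEIS1 at -1.85 ± 0.31, and the list's median was -0.56, at percentile 0.10. MEIS1 and MEIS2 encode cofactors of HOX proteins. Midbrain and isthmus genes had a median of 0.06 over 5 detected, with SPRY1, an FGF feedback inhibitor, higher at 1.62 ± 0.35 and PAX8 lower at -1.33 ± 0.35. In the retinoid list 1 of 10 genes was higher, CYP26A1 at 1.19 ± 0.25, which was 2.45 against the first array's HSF6 channel, and 2 were lower, including CRABP1, a retinoic acid-binding protein, at -2.76 ± 0.33, with a median of -0.11. In the BMP list 2 of 12 genes were lower, the secreted inhibitor FST at -1.13 ± 0.29 and the target ID2 at -1.10 ± 0.24, which was -0.74 against the first array's HSF6 channel. The list's median was -0.23, and that of 7 targets alone was 0.0080. In the Wnt, FGF and SHH list 3 of 10 were higher, among them SP5 by at least 3.97-fold and LEF1 at 1.59 ± 0.26, with a median of 0.46.

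Several neuronal and glial genes were lower in HSF1 monolayer than in HSF6 EB cells. CNTN2 at -2.93 ± 0.37 and neurofilament NEFM at -2.74 ± 0.34 were among 4 of 19 neuron genes past 2-fold, with a list median of -0.25 that was 0.0074 after median centring. CNTN2 stood at -1.63 against the first array's HSF6 channel. GFAP at -2.49 ± 0.36 and S100B at -2.12 ± 0.42 were among 3 lower and 1 higher of 6 glial genes, whose median was -0.46. In the progenitor list 3 of 17 genes were higher and 2 lower, SLC1A3, a glutamate transporter of radial glia, at -2.78 ± 0.35 and SOX3 at -1.07 ± 0.23, with a median of 0.03. Against the first array's HSF6 channel the SOX3 ratio was 1.59. PAX3 was the 1 gene lower among 7 of the neural crest list, at -1.98 ± 0.35, and stood at -0.56 against that channel, and that list's median was -0.09. All 16 cell cycle genes again had positive ratios, with a median of 0.59 above all random lists, and TYMS and TOP2A passed 2-fold at 1.24 ± 0.24 and 1.03 ± 0.23.

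Among non-neural groups, collagen COL1A2 was lower at -3.02 ± 0.36 and FOXC1 higher at 2.53 ± 0.36, among 3 lower and 2 higher of 13 mesenchyme genes with a median of -0.60. FOXC1 stood at 0.965 against the first array's HSF6 channel, its HSF6 signal differing by -1.56. The keratin KRT19 was higher at 2.55 ± 0.45, 1 of 5 epithelial and trophoblast genes, with a median of 0.65. DLK1, an imprinted gene for a Notch ligand-like protein, had a ratio of 4.56 ± 0.52 and MEST was at least 8.35-fold lower, the only genes past 2-fold of 12 imprinted genes with a median of 0.13. Of 12 stress genes 4 were higher, among them ATF3 at 1.74 ± 0.28 and HSPA1A at 3.18 ± 0.39, and the median was 0.15. HSPA1A is uncertain because HSPA1B is a near-identical copy, and its HSF6 signal differed by -2.36 between the arrays, with a ratio of 0.82 against the first array's HSF6 channel. Among 12 housekeeping genes B2M was lower at -1.83 ± 0.27, and their median was -0.11. No gene passed 2-fold among 7 pluripotency genes (median -0.01) and the 2 endoderm genes detected, CXCR4 at 0.44 ± 0.21 and SOX17 at 0.02 ± 0.28, and 0 blood and endothelial genes were detected.

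In all, 163 genes were higher and 350 lower in HSF1 monolayer than in HSF6 EB cells, of 10792 detected. Among the highest ratios were those of LHX2, with its probe on chromosome 9 at 123874811 to 123874870, DLK1, EMX2OS at 4.39 ± 0.61, EMX2 and RSPO1, a Wnt agonist, at least 15.02-fold higher. The lowest were those of the matrix protein TGFBI at -5.06 ± 0.55, with its probe on chromosome 5 at 135427242 to 135427301, LAMP5 at -4.21 ± 0.61, HOXB3, MAGEH1 at -3.71 ± 0.51, the hyaluronan receptor CD44, at least 11.1-fold lower, and GPM6B at -3.56 ± 0.44. With median centring in place of loess, 743 genes were higher and 175 lower, 80.9% higher against 31.8%, and the median of detected genes stood at 0.27. Against the first array's HSF6 channel 408 were higher and 648 lower, and 391 of the 513 genes kept their call. Of the 43 calls among genes chosen by the naming rule, 37 were kept, 5 fell under 2-fold and 1 changed sign.

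The third comparison asked how HSF1 progenitors differed by route. It took the difference of the arrays' log2 ratios, so that a probe's dye effect cancelled, and was set beside the plain difference of the Cy5 signals. The first of these carries any difference between the HSF6 samples and the second carries any difference between the arrays. All 17 detected forebrain genes had positive ratios in HSF1 monolayer over HSF1 EB cells, with 7 past 2-fold. Their median of 0.75 lay above all 10000 random lists, and it was 1.17 in Cy5 alone, where 11 genes passed 2-fold. With no filter on background it was 0.38, and over genes well above background in every channel it was 0.45. For 9 of the 17 only 1 Cy5 channel was well above background. EMX2 was at least 27.5-fold higher in Cy5 and FEZF2 at least 4.69-fold, with smaller ratios of 4.0005 ± 1.34 and 1.83 ± 1.51 through HSF6, and LHX2 had a ratio of 4.45 ± 0.89 through HSF6 and 4.41 in Cy5.

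HOX genes differed less clearly by route. Of 12 detected 3 were lower, HOXB2 at -1.96 ± 0.49, HOXA2 by at least 3.15-fold and HOXB3 at -1.62 ± 0.66, with another HOXB2 probe of the opposite sign. Another 3 were higher through HSF6, HOXB4 at 1.0004, HOXB5 at 1.21 and HOXD3 at 1.54 ± 0.64. In Cy5 alone 6 HOX genes were lower and 0 higher, and HOXB4, HOXB5 and HOXD3 stood at -0.23, -0.33 and -0.30. Their HSF6 signals differed by -1.23, -1.54 and -1.85 between the arrays, and none was well above background in HSF1 monolayer cells. The list's median was -0.34 through HSF6, at percentile 0.030, and -0.92 in Cy5. With no filter on background it was 0.0082. In the list of hindbrain and spinal cord genes outside the HOX family 4 of 9 were lower, among them MEIS1 at -1.54 ± 0.37 and MEIS2 at -1.12 ± 0.45. That list's median of -0.93 lay below all random lists and was -0.60 with genes at their bound and -1.04 in Cy5. Midbrain and isthmus genes had a median of -0.50 over 7 detected, which was 0 with genes at their bound and -0.28 in Cy5, with SPRY1 higher at 1.76 ± 0.42 and EN2 at -0.84 ± 0.30.

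Most genes of the BMP list had negative ratios in the Noggin-treated monolayer cells over HSF1 EB cells, few of them past 2-fold. Of 14 detected 13 were negative and 3 passed 2-fold, among them the targets ID2 at -1.78 ± 0.32 and BAMBI at -1.34 ± 0.31, and the median of -0.57 lay below all random lists and was -0.72 in Cy5. BAMBI stood at -0.99 in Cy5. Of the 9 targets alone 8 had negative ratios and 2 passed 2-fold, with a median of -0.53 and of -0.68 in Cy5, and the other 5 genes are ligands and inhibitors. In the retinoid list 4 of 12 genes were lower and 2 higher, with CRABP1 at -2.11 ± 0.39 and CYP26B1 at -1.85 ± 0.38, and the median was -0.21. In Cy5 alone 3 of them were lower and 0 higher, with a median of -0.56. In the Wnt, FGF and SHH list 2 of 14 were lower, AXIN2 at -1.01 ± 0.30 and SHH, with a median of 0.05. SHH was not well above background in HSF1 monolayer cells and was at least 1.25-fold lower there in Cy5, which does not reach 2-fold. In Cy5 AXIN2 stood at -0.30, 1 gene of the list was higher and 0 were lower, and the median was -0.25.

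The neural crest genes PAX3 at -3.49 ± 0.45 and TWIST1 at -1.73 ± 0.36 were lower in HSF1 monolayer than in HSF1 EB cells, and the median of 8 such genes was -0.44. In Cy5 PAX3 stood at -2.08, 4 of them were lower and 0 higher, and the median was -0.77. The progenitor genes SLC1A3 at -3.34 ± 0.41 and SOX3 at -2.95 ± 0.36 were among 3 lower and 1 higher of 18. SOX3 stood at -0.28 in Cy5, where 3 of the list were higher and 2 lower, and that list's median was -0.21 through HSF6 and 0.43 in Cy5. Neurofilaments NEFM at -2.24 ± 0.40 and NEFL at -1.24 ± 0.35 were among 3 lower and 2 higher of 19 neuron genes with a median of -0.0019, against 3 lower and 0 higher in Cy5, and another NEFM probe had the opposite sign. S100B at -1.85 ± 0.47 and PDGFRA at -1.79 ± 0.39 were among 3 lower of 7 glial genes, with a median of -0.28, against 2 lower, 1 higher and a median of -0.44 in Cy5. The keratins KRT19 at 3.12 ± 0.53 and KRT18 at 2.28 ± 0.34 were among 3 higher and 1 lower of 6 epithelial and trophoblast genes, whose median was 1.003. In Cy5 KRT18 stood at 1.096, 3 of them were higher, 0 were lower, and the median was 0.71.

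DLK1 had a ratio of 4.50 ± 0.56 and was 1 of 3 higher and 1 lower of 11 imprinted genes, with a median of 0.09. H19, at 2.31 ± 0.59 through HSF6, stood at -1.54 in Cy5, at least 2.30-fold lower, where 1 imprinted gene was higher and 3 were lower. IGF2 likewise stood at 2.02 through HSF6 and -2.44 in Cy5. In the mesenchyme list, with 2 higher and 3 lower of 13 and a median of -0.06, COL1A2 stood at -1.59 ± 0.44, with another probe of the opposite sign, and DCN at 1.47 ± 0.33 through HSF6 and -0.56 in Cy5. In Cy5 alone 7 mesenchyme genes were lower and 0 higher, and the median was -1.17. HSPA1A at 3.07 ± 0.44, uncertain as above, stood at 0.71 in Cy5, and ATF3 at 1.09 ± 0.35 was the other stress gene past 2-fold of 11, with a median of 0.03 and of -0.28 in Cy5. TTR had a ratio of -2.70 ± 1.13 through HSF6 and was at least 9.67-fold lower in Cy5. It was 1 of 3 endoderm genes, with a median of -0.21 and of -0.66 in Cy5. Through HSF6 no gene passed 2-fold among 16 cell cycle genes, whose median was 0.22 with BUB1 at 0.55 ± 0.32, or among 7 pluripotency genes, whose median was 0.23, or 0.09 with genes at their bound. In Cy5 the cell cycle median was 0.73 with 1 gene higher, and TERT was the 1 pluripotency gene higher, at 1.08. Of 12 housekeeping genes HPRT1 was higher at 1.44 ± 0.35, though 0.56 in Cy5, and B2M lower at -1.14 ± 0.35, with a median of -0.07, and 0 blood and endothelial genes were detected.

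In all, 176 genes were higher and 252 lower in HSF1 monolayer than in HSF1 EB cells, of 11497 detected. Besides DLK1, LHX2 and EMX2, the highest included TNNT1, a slow-muscle troponin, at 4.19 ± 0.52 and EMX2OS at 3.68 ± 0.93. TNNT1 stood at 1.45 in Cy5. The lowest through HSF6 were the Wnt receptor gene FZD10 at -4.15 ± 0.42, with its probe on chromosome 12 at 129175054 to 129175113, the growth factor gene GDF10 at -3.77 ± 0.42, the protocadherin PCDH8 at -3.50 ± 0.40, PAX3, PRDM13, at least 3.26-fold lower in Cy5, and TGFBI at -3.36 ± 0.61. In Cy5 TGFBI was the lowest of these at -4.28, and FZD10, GDF10 and PCDH8 stood at -2.75, -2.84 and -2.21. In Cy5 alone 192 genes were higher and 404 lower. Of the 176 higher genes 83 were also higher in Cy5, and of the 252 lower genes 175 were also lower. Of the 45 calls among genes chosen by the naming rule, 35 were kept in Cy5, 7 fell under 2-fold and 3 changed sign.

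**Figure D2:**
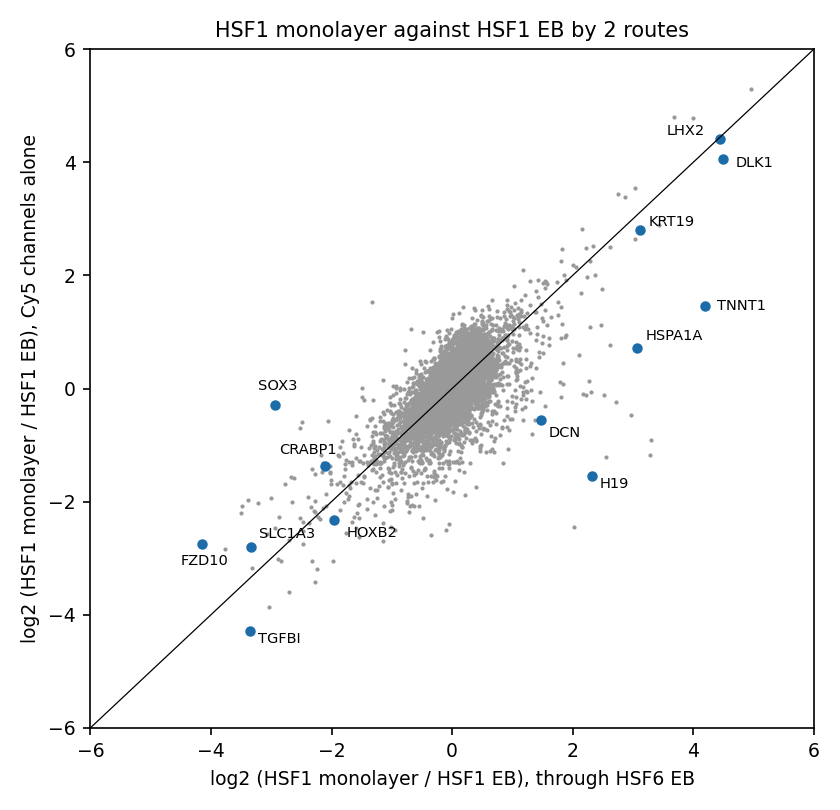
Log2 ratio of HSF1 monolayer over HSF1 EB cells through the HSF6 channel (horizontal) against the difference of the Cy5 signals alone (vertical), 1 point per detected gene, with the line of equality. LHX2 and DLK1 lie near the line, at 4.41 and 4.06 in Cy5, and H19, DCN, HSPA1A, SOX3 and TNNT1 lie away from it.

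The ratios of HSF1 over HSF6 on the arrays were correlated across 10647 genes detected on both, with Pearson's r of 0.56 and Spearman's rho of 0.60. Genes are not independent replicates. Both ratios share the HSF6 side, and unchanged samples simulated around a shared HSF6 sample gave r of 0.50. That value follows from giving every simulated sample the same spread and was not learned from these arrays. The covariance was 0.11 against 0.07 simulated. Of the genes detected on both arrays, 30 were higher in HSF1 on both and 116 were lower on both. The same 100 simulations gave 34 to 59 genes higher on both and 27 to 64 lower on both. The spread used in the simulation also holds differences between the arrays that cancel within a ratio. With each ratio taken against the HSF6 channel of the other array r was 0.03, a setting that adds such differences in opposite directions.

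**Figure D3:**
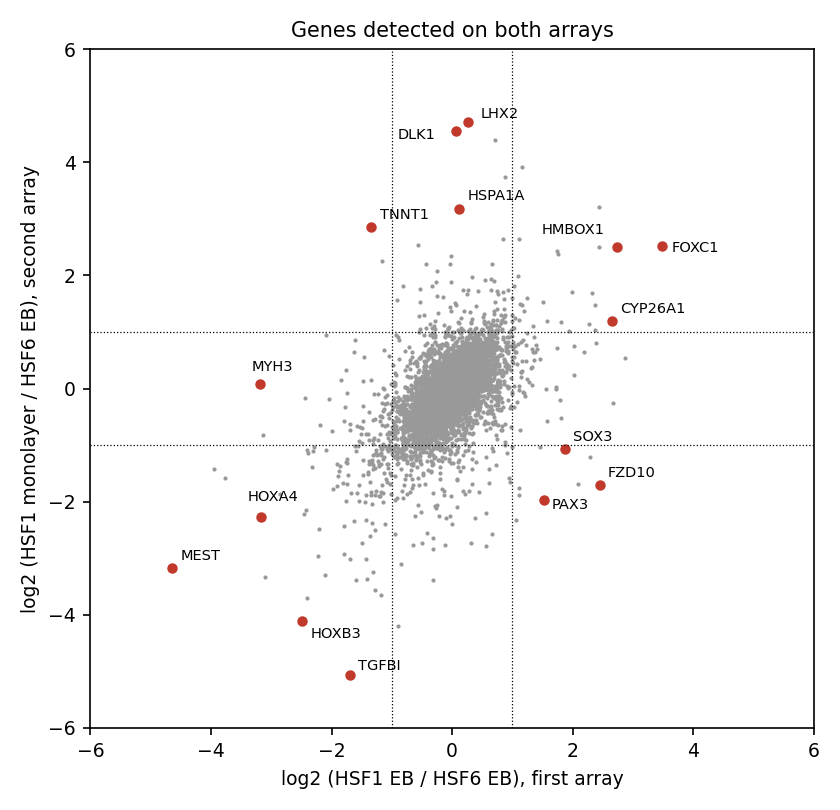
Log2 ratios of HSF1 EB over HSF6 EB (horizontal, first array) and HSF1 monolayer over HSF6 EB (vertical, second array), 1 point per gene detected on both arrays. Dotted lines mark 2-fold, with MEST, HOXA4 and HOXB3 low on both arrays, FOXC1 and HMBOX1 high on both, LHX2 and DLK1 high on the second only, and PAX3, FZD10 and SOX3 of opposite sign.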

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

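In this part, the tests of an array effect shared by both dyes, of marks on the slide and of HSF6 differences behind opposite ratios were chosen after the results were seen.

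Among the named genes 7 had ratios of opposite sign on the arrays, each at least 2-fold. The difference was not tested, since each value comes from 1 array. HSF1 over HSF6 was 2.45 in EB cells and -1.70 in monolayer cells for FZD10, 2.08 and -1.69 for GDF10, 1.52 and -1.98 for PAX3, and 2.29 and -1.20 for PCDH8. It was 1.06 and -2.32 for PRDM13, which was not well above background in monolayer cells and at least 4.16-fold lower there, 1.87 and -1.07 for SOX3, and -1.34 and 2.85 for TNNT1. Over all genes 11 behaved in this way, and 81.8% of them were also at least 2-fold apart in the same direction between the HSF1 channels alone. This argues against a difference in the HSF6 material as the whole cause of the gap between their ratios, though not of the opposite sign. The exceptions were SOX3 and TKTL1, at -0.28 and -0.59 in Cy5, where HSF6 differed by 2.66 and 1.90. The opposite sign itself rested on the HSF6 channel for some genes. Against the second array's HSF6 channel the EB ratio was 1.39 for TNNT1, -0.35 for PRDM13, -0.79 for SOX3 and -0.44 for TKTL1. These have the sign of the monolayer ratios. For PAX3 at 0.10, FZD10 at 1.04 and PCDH8 at 1.01 the EB ratio stayed positive, opposite to the monolayer ratio. The monolayer ratios depended on the channel too. The HSF6 signal of PCDH8 was 1.29 higher on the second array, which exceeds the size of its monolayer ratio of -1.20. Against the first array's HSF6 channel that ratio is therefore not negative. The monolayer ratio of PAX3 was -0.56 against that channel, and FZD10's HSF6 signal was 1.41 higher on the second array. The route of neural induction, which the design names, remains open for the genes apart in Cy5 and was not tested with replicates.

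The HSF6 EB channel differed between the arrays, most for IGF2 (-4.46, second minus first), MYH3 (-4.45), MYBPH (-4.22), H19 (-3.85) and the troponin TNNC2 (-3.77), genes named here after their values were seen. Spot or probe noise was argued against, since a second probe went the same way for 82.8% of 64 genes. An array effect shared by both dyes cannot be told apart from a real difference, because the Cy5 channels differed in the same direction by 64.3% as much in the median (-0.88 beside -1.30 for the 212 dimmer genes, and 0.38 beside 1.21 for the 52 brighter, with 13 of these higher and 10 lower by 2-fold), and HSF1 monolayer and EB cells may differ there too. Skeletal muscle cells in the HSF6 material of the first array are a candidate source: 16 detected genes of 24 held-out muscle markers, 5 of them also detected in HSF1 and 0 in another list, had a median difference of -0.90, below all random lists, with 7 lower by at least 2-fold, among them ACTC1 (-1.09) and TNNC1 (-1.59). MYOD1 (0.0087) and MYH7 (0.064) did not differ in that way, the same markers had a median of 0.09 in Cy5, most of them near background there, and muscle is not singled out, since the mesenchyme list differed by -1.14 (7 of 13 lower by 2-fold) and by -1.17 in Cy5. Most of the 16 had second-array HSF6 signals under 6.22, the lowest of any probe well above background there, TNNC1 among them. These passed the filter only through the first array, where they were brighter. The random lists were not matched on this, so the median and its rank rest partly on the filter.

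On the first array 41 spots were at least 4-fold brighter in Cy5, and 16 of them had another such spot within 3 rows and 3 columns, against a median of 2 and a highest value of 12 in 1000 shuffles of positions. On the second array 0 of 33 such spots had one. A local mark on the slide is a candidate cause, with VENTXP1 and LY6G6E among the genes concerned and second-array ratios of 0.02 and 0.01. Expression of these genes in HSF1 EB cells was argued against as the whole cause, since it does not follow position and the count of 16 lay above every shuffle, and 0 of the 3 that have another probe were at least 2-fold higher there. It stays open for single genes among them.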

How the results depend on the processing

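The HSF6 channel of the other array, the removal of clustered spots and the BMP targets without ligands and inhibitors were chosen after the data were examined. Values are log2 unless they are counts, pairs of counts are higher then lower, and causes were not tested except where stated. Over the alternatives the forebrain median stayed positive for HSF1 monolayer against HSF6 EB (0.38 to 2.72) and against HSF1 EB (0.38 to 1.77), and the HOX median stayed negative for HSF1 EB (-2.02 to -0.30) and HSF1 monolayer (-3.91 to -0.15) against HSF6 EB. Without background correction and with outlier-marked spots kept, the counts of all 3 comparisons stayed within 1.5 times, as did those of HSF1 EB against HSF6 EB and HSF1 monolayer against HSF1 EB without clustered spots, a setting not run for the other comparison. Signal over background limits all dim genes: the offset damps their ratios, as its construction shows.

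With offset 0 the counts were 402 and 589 for HSF1 EB against HSF6 EB, 427 and 717 for HSF1 monolayer against HSF6 EB, and 367 and 626 for HSF1 monolayer against HSF1 EB. The forebrain medians of the last 2 comparisons were 1.63 and 1.02, and the HOX medians of all 3 were -1.83, -3.38 and -1.42. In the same order, the scanner software's log ratio gave 578 and 850, 676 and 971, and 544 and 842, with forebrain medians of 2.72 and 1.77 and HOX medians of -2.02, -3.91 and -1.86. The series table gave 577 and 850, 675 and 969, and 544 and 842, with 2.72 and 1.77, and -2.02, -3.90 and -1.86. Median centring gave 349 and 135 in the first comparison and 743 and 175 in the second, and a neuron median of 0.0074 in the second.

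Among genes well above background in every channel compared, 91 were higher in HSF1 EB than in HSF6 EB and 116 in HSF1 monolayer than in HSF1 EB, a filter that leaves fewer genes. There the forebrain medians were 0.72 and 0.45 for HSF1 monolayer against HSF6 EB and against HSF1 EB, the HOX medians -3.37 and -1.62, the midbrain and isthmus median -0.15 in the first and the pluripotency median -0.019 for HSF1 monolayer against HSF1 EB. These HOX medians are the values of single genes, HOXB2 and HOXB3. The filter left out at least 11 of 14 and 9 of 12 detected HOX genes in those comparisons. With no filter, which adds genes near background, the correlation was 0.50, the forebrain medians 0.38 and 0.38, and the HOX medians -0.30, -0.15 and 0.0082. The mean of a gene's probes gave 91 genes higher in HSF1 EB than in HSF6 EB, and medians of 0.88 for forebrain and -1.39 for HOX in the second comparison.

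In Cy5 alone 404 genes were lower in HSF1 monolayer than in HSF1 EB, the forebrain median was 1.17, the HOX median -0.92, the progenitor median 0.43, HOXD3 -0.30, DCN -0.56 and H19 -1.54. Against the HSF6 channel of the other array 241 genes were higher in the first comparison, and 408 were higher and 648 lower in the second. The correlation was 0.031 and the HOX median of the first comparison -0.85. Other medians of the first comparison became -0.22 for progenitor, 0.017 for neuron, 0.42 for mesenchyme and -0.13 for cell cycle genes. MYBPH stood at 0.89, MYH3 at 1.26, HES5 at -0.50, SOX3 at -0.79, FN1 at 0.63 and H19 at 0.71, and SOX3 at 1.59 in the second comparison. Of 1672 values of named genes under an alternative, 1202 moved by less than the scanner error, 460 by more, and 10 values of called genes changed sign, 3 of them to at least 2-fold the other way. The BMP targets alone had medians of 0.54, 0.0080 and -0.53, against 0.44, -0.23 and -0.57 for the list.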

Other observations

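The genes in the first paragraph were picked after their values were seen, from among those with large ratios in the same direction on both arrays, and are not the full ranking. Besides genes already described, TBX1, a transcription factor of pharyngeal and ear development, had an HSF1 over HSF6 ratio of 2.44 ± 0.34 in EB cells and was at least 9.26-fold higher in monolayer cells, and the neuropeptide gene NMU had ratios of 2.44 ± 0.37 and 2.51 ± 0.36. The cartilage collagens COL2A1 and COL9A3 were higher as well, at 1.76 ± 0.28 and 2.39 ± 0.34 and at 1.75 ± 0.27 and 2.44 ± 0.38. TMEM121 was lower at -3.10 ± 0.39 and -3.33 ± 0.49. The imprinted gene NNAT, which was in no list, was lower at -2.23 ± 0.41 and by at least 6.54-fold, on both arrays like MEST. The matrix gene TNC was lower at -2.11 ± 0.29 and -3.30 ± 0.40, MFAP4 at -1.79 ± 0.27 and -2.43 ± 0.34, and the DNA repair gene MGMT by at least 3.45-fold and 2.56-fold. These ratios share the HSF6 side and the dye orientation, so neither a difference in the HSF6 material nor a dye effect was excluded for them.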
